A study of Mus musculus with 26 samples.

How the data were processed

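The data were 2-colour NimbleGen tiling arrays of genomic DNA from 26 mouse lymphomas, 1 array each, with tumour DNA labelled with Cy3 and reference DNA with Cy5, per the labels. The labels name separate tumours and do not say that each came from its own animal, so p-values measure the spread between these tumours. The strain was mixed FVB and 129Ola, per the labels. Each array came with a probe table, a table of single probes sorted by position and a table of 60 kb windows, and the series matrix held the same probe values. All values used were on a log2 scale, per the file headers and the range of the values. The authors deposited, for each of 385079 probes, the log2 signal of both channels, the log2 ratio of tumour over reference, spatially corrected values, normalized signals of both channels and the corrected log2 ratio. The corrected ratio equalled the normalized tumour signal minus the normalized reference signal to within 0.001, so its direction was tumour over reference on every array, and no dyes were swapped. The deposited windows were a Tukey biweight average of the corrected probe ratios, as recomputing them gave the same values to within 8e-05. The series matrix differed from the corrected probe ratios by at most 0.0005. The spatial step changed the values of 10 late arrays and left those of 16 early arrays as they were, and the array numbers in the deposited files fall into the same 2 batches. The only tool the submitters' processing notes name is affy, without a version. The normalization method and the genome build are not given in the sources used here. The last probe of chromosome 1, at 197064247, lies beyond the last gene of GRCm38 at 195291439, so the files do not use GRCm38. Coordinates are printed as the files give them, and the GRCm38.p6 gene table served only to name the chromosome that carries each gene. Of the fixed lists, 3 loci are not reported here, and the lists were counted without them. All remaining loci were found in the gene table. Their positions within chromosomes were not used here, so the planned tests of single loci were not run.

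The groups were taken from the labels. For tumour T61 the description gives Palb2+/+ and the source labels of both channels give Palb2GT/+, and the group was set by the numbers of tumours the study states. The protocol in the labels also mentions a reference pooled from males, whereas the other labels and the design name tissue of the same animal. Apart from T560, the Y signal of the reference channel was low on 12 arrays (at most -0.961 relative to the autosomes) and high on 13 (at least 0.391), in each case as in the tumour channel, so the reference did not have the same Y signal on every array. These values argue against a reference pooled from males for the 12 arrays with low signal. For the 13 with high signal they do not decide. The raw ratios had array medians from 0.188 to 0.989 and the corrected ratios from -0.019 to 0.013. The main analysis used the deposited windows (39439 autosomal, 2481 on chromosome X, median 10 probes per autosomal window), with each array centred on its autosomal median and no further normalization. Correlations between arrays ranged from -0.237 to 0.632, and no 2 arrays were identical.

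The plan, fixed before the data were examined, assumed deposited segment means. The files used here hold windows and not segments, so segments were computed. Each chromosome was divided by an exact least-squares partition weighted by probe number, with a cost per segment of 3 times the squared noise SD times the natural log of the number of windows and a minimum of 3 windows (180 kb). A window was gained or lost at a segment mean at least 0.2 from 0. Breakpoints were boundaries of segments differing by at least 0.2, whole-chromosome changes covered at least 80% of windows, and focal segments were at most 3 Mb long and at least 0.4 from 0. Recurrent regions were stretches covered by focal segments of 1 sign in at least 3 tumours. Values per tumour and chromosome means were compared between genotypes with two-sided permutation tests (100000 resamples), chromosome means in all tumours with sign-flip permutation, and groups under 10 with exact permutation tests. Windows were compared with limma 3.58.1 in R 4.3.3, and frequencies with Fisher's exact test. Adjustment was by Benjamini-Hochberg, and intervals of mean differences came from 10000 bootstrap resamples. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

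The text names every chromosome past an adjusted p of 0.05 in all tumours, the 3 with the smallest p by genotype, the 10 recurrent focal regions in most tumours (7 were found) and fixed lists of antigen receptor loci, homologous recombination genes, oncogenes and tumour suppressors. High-level segments, the distal chromosome 12 windows and single tumours were chosen after their values were seen. The alternatives covered thresholds, centring, array batch, reference tissue, the genotype of T61, noisy arrays, bin size, probe minimum, segment means and probe values. Segmentation costs of 2 and 6, ratios before the authors' normalization, tumours T560, T98 and T105 left out, focal segments measured from the median of their own chromosome, and the test of any gained or lost segment per chromosome were added after the data had been seen.

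The steps were tested on simulated data. For the segments, the simulated noise had the SD of each array. For limma, each window was drawn with its real mean and SD over the arrays. The permutation test was given standard normal values. All draws came from normal distributions and were independent between windows. At a change of 0.4, 71.2% of segments of 3 windows and 100.0% of segments of 10 windows were found. At 0.2 these shares were 1.0% and 52.9%. A segment counted as found from a mean of 0.2 for a change of 0.4 and of 0.1 for a change of 0.2. Calls required 0.4 for focal segments and 0.2 for gains and losses, so the share called at the threshold itself was not measured. The 104 flat profiles of 2000 windows gave 0 false boundaries. Noise shared by neighbouring windows was not simulated, so false boundaries from it were not tested. For the windows by genotype, limma recovered 82 of 100 windows changed by 0.3 and 100 of 100 changed by 0.6 among 39439, and called 6 unchanged windows. The permutation test gave p under 0.05 for 6.2% of 500 unchanged values.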

Results

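Copy number was measured by array comparative genomic hybridisation in 26 mouse lymphomas that had arisen in animals without p53, the tumour suppressor encoded by Trp53. Of these, 15 came from animals that also carried 1 altered allele of Palb2, written Palb2GT/+ in the labels, and 11 came from Palb2+/+ animals. Palb2 encodes a partner of Brca2 in the repair of DNA double-strand breaks by homologous recombination. Tumour DNA (Cy3) was hybridised together with spleen or liver DNA (Cy5), stated to be from the same animal, on a tiling array of 385079 probes, and every value below is a log2 ratio of tumour over reference. The reference was spleen on 20 arrays and liver on 6. Each lymphoma gave 1 array. The 26 arrays fell into an early batch of 16 and a late batch of 10, and the 6 liver references were all in the late batch. The noise of single 60 kb windows, as the SD of neighbouring values, ranged from 0.072 to 0.138 with a median of 0.096, and the number of arrays limits the precision of every comparison between groups. The labels of 1 tumour, T61 (Palb2+/+ replicate 7), disagreed on its genotype. It was kept among the Palb2+/+ tumours, since only that gives the 15 and 11 tumours that the study states.

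The first question was which chromosomes were gained or lost in these lymphomas, whatever the genotype. Chromosome 15, which carries Myc, a transcription factor that drives proliferation, was the most frequently gained. Its mean log2 ratio was 0.17 ± 0.12 (SD, n = 26), it was above 0 in 23 of 26 tumours, and 7 tumours had gained at least 80% of it at a segment mean of 0.2 or more. Chromosome 4 (0.097 ± 0.13, whole gain in 3 tumours), chromosome 5 (0.091 ± 0.099, whole gain in 1) and chromosome 11 (0.058 ± 0.089, whole gain in 1) were also above 0. Chromosome 19 was below 0 at -0.083 ± 0.12, with whole loss in 2 tumours and a lost segment of any size in 18. Chromosome 3 lay below 0 in 24 of 26 tumours at -0.057 ± 0.049, although no tumour reached the criterion for whole loss. A lost segment of any size was present there in 4 tumours. In the 4 tumours with less than 1% of the autosomes altered, the mean of chromosome 3 was from -0.024 to -0.012. A small shift shared by the arrays was therefore not told apart from loss.

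In a two-sided sign-flip permutation test with Benjamini-Hochberg adjustment over 20 chromosomes, 12 chromosomes differed from 0. The adjusted p was 0.0001 for chromosomes 3 and 15, for which the unadjusted p of 1e-05 is the smallest the permutations can give. It was 0.00175 for chromosome 4, 0.000533 for chromosome 5, 0.00407 for chromosome 11 and 0.003 for chromosome 19. The other 6 all had a mean below 0. These were chromosome 6 (-0.037 ± 0.065, adjusted p = 0.016), chromosome 7 (-0.025 ± 0.049, 0.0267), chromosome 8 (-0.038 ± 0.064, 0.0115), chromosome 9 (-0.035 ± 0.054, 0.002), chromosome 13 (-0.046 ± 0.064, 0.002) and chromosome X (-0.063 ± 0.13, 0.0267). Which of the small shifts passed the test depended on the centring. Of the 12 calls, 4 were above and 8 below 0 with centring on the median, and of the 9 calls with centring on the mode of the windows, 7 were above 0 (chromosomes 1, 2, 4, 5, 11, 14 and 15) and 2 below (3 and 19). The calls for chromosomes 6, 7, 8, 9, 13 and X ended with that centring (adjusted p from 0.0753 to 0.668), whereas chromosomes 3, 4, 5, 11, 15 and 19 stayed past the threshold under all 6 alternatives tried for them. Chromosome X also lost its call without tumour T560 (Palb2GT/+ replicate 1), whose sex chromosomes did not match those of its reference (mean -0.048, adjusted p = 0.0532), and its mean was 0.058 on the ratios before the authors' normalization (adjusted p = 0.137).

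**Figure D1:**
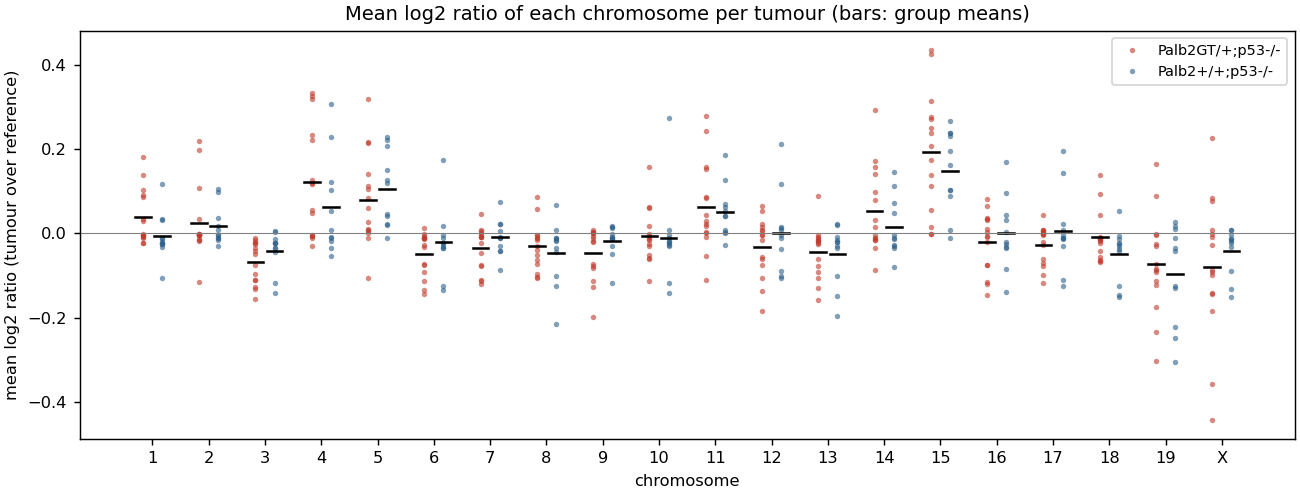
Mean log2 ratio (vertical axis) of each chromosome (horizontal axis) in each of the 26 lymphomas, with a point per tumour coloured by genotype and a black bar for each group mean. Chromosome 15 was above 0 in 23 tumours and chromosome 3 below 0 in 24. The largest gap between the group means of the genotypes was 0.0597, on chromosome 4.

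Focal losses recurred at 3 places. Coordinates are those of the deposited files, whose genome build is not given in the sources used here. The first, on chromosome 14 from 52620000 to 53159999, was lost in 15 of 26 tumours with a mean log2 ratio of -0.64 ± 0.24 (SD, n = 15) in those tumours. The second, on chromosome 6 from 41100000 to 41459999, was lost in 13 tumours at -0.56 ± 0.15 (n = 13). The third, on chromosome 19 from 32340000 to 33239999, was lost in 10 tumours at -0.53 ± 0.27 (n = 10). A focal loss on chromosome 6 or 14 was present in 19 tumours, and 9 tumours had both. Counting lost segments of any size, the window that was lost most often in the genome lay on chromosome 14 at 52949999, in 20 of 26 tumours. Chromosome 14 carries the T-cell receptor loci Tcra and Tcrd, and chromosome 6 carries Tcrb. With no annotation of the files' build, these loci could not be placed within the lost regions.

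**Figure D2:**
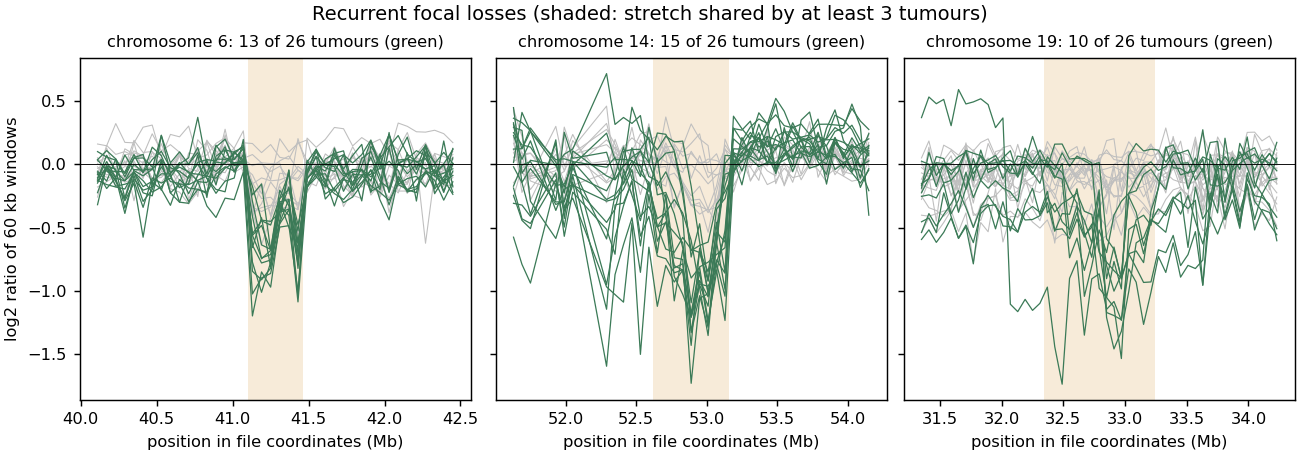
Log2 ratio of 60 kb windows (vertical axis) along 3 stretches of chromosomes 6, 14 and 19 (horizontal axis, Mb in file coordinates), with a line per tumour. Green lines are the 13, 15 and 10 tumours with a focal loss there, grey lines the remaining tumours, and the shaded stretch is the region covered by focal losses of at least 3 tumours.

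Focal gains recurred at 4 places, each in 3 tumours. On chromosome 12, from 112980000 to 113759999, the 3 tumours had a mean of 1.55 ± 0.66 (n = 3), and all 3 were Palb2GT/+. On chromosome 16, the regions from 87060000 to 88379999 (0.83 ± 0.099, n = 3) and from 97200000 to 98265277 (0.84 ± 0.23, n = 3) were gained in the same 3 tumours, T560, T61 and T174 (Palb2+/+ replicate 9). On chromosome 2, from 24420000 to 26339999, the mean was 0.63 ± 0.16 (n = 3). Chromosome 2 carries Notch1, chromosome 12 carries Igh, Mycn and Bcl11b, and chromosome 16 carries Igl and Runx1, none of which could be placed relative to these regions. The 3 focal losses were found under all 8 alternative settings for focal regions, in 8 to 18 tumours each. Each gain was in 3 tumours, the smallest number that makes a region, so leaving out any of them ends it. The count of regions itself ranged from 3 to 16 over these settings, against 7 here.

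Some changes were of high level. A criterion of a segment mean of 1 or more, chosen after the profiles had been seen, was met in 11 tumours, of which 7 of 15 were Palb2GT/+ and 4 of 11 Palb2+/+ (Fisher's exact test, two-sided, p = 0.701). The highest segment, at 2.66, was 1 of 4 amplified segments on chromosome 12 between 112560000 and 113879999 in tumour T176 (Palb2GT/+ replicate 12). On chromosome 7, tumour T095 (Palb2GT/+ replicate 15) had 5 amplified segments between 112500000 and 115919999 with a maximum of 2.62, and tumour T100 (Palb2+/+ replicate 3) reached 1.66 between 113340000 and 113939999. Chromosome 16 held amplified segments in 4 tumours, T560, T98 (Palb2+/+ replicate 4), T61 and T174, and in T98 it held 8 separate amplified segments with a maximum of 2.15.

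The loci fixed in advance were followed through the chromosome that carries each, as listed in the GRCm38.p6 gene table, because their positions in the files' build were not used here. The counts therefore describe chromosomes, not the genes. Of 12 lymphoma oncogenes, 3 lay on chromosomes with a mean above 0 (Myc on 15, Cdk6 on 5 and Tal1 on 4), 1 on chromosome 6, below 0 (Ccnd2), and 8 on chromosomes that did not pass the test. Of 15 lymphoma tumour suppressors, 5 lay on chromosomes above 0 (Cdkn2a and Pax5 on 4, and Ikzf1, Ebf1 and Nf1 on 11), 5 on chromosomes below 0, among them Fbxw7 and Lef1 on 3, and 5 on neither. Of the 9 genes in the list of Palb2, Trp53 and homologous recombination partners, 6 lay on chromosomes above 0 (Trp53, Brca1, Brip1 and Rad51c on 11, Brca2 and Chek2 on 5), 2 on chromosomes below 0 (Palb2 on 7 and Atm on 9), and 1 on neither. Of the 7 antigen receptor loci, 3 lay on chromosomes below 0 (Tcrb and Igk on 6, Tcrg on 13) and 4 on neither. The calls for chromosomes 6, 7, 9 and 13 are among those that ended with centring on the mode, which also added calls above 0 for chromosomes 1 (Bcl2 and Bard1), 2 (Notch1, Lmo2 and Gata3) and 14 (Tcra, Tcrd and Rb1).

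At the level of single tumours, a loss of the Myc-bearing chromosome 15 was not seen: all 26 tumours were free of a lost segment there. On the chromosomes of the T-cell receptor loci, a lost segment of any size was present in 20 tumours on chromosome 14, in 16 on chromosome 6 and in 5 on chromosome 13. On those of the immunoglobulin loci Igh and Igl, which rearrange in B cells, it was present in 9 tumours on chromosome 12 and in 10 on chromosome 16, and Igk shares chromosome 6 with Tcrb. The tumours with a loss on chromosome 12 were 8 of 15 Palb2GT/+ and 1 of 11 Palb2+/+ (Fisher's exact test, p = 0.0362, Benjamini-Hochberg adjusted p = 1.0 over 40 tests of gain or loss per chromosome, chosen after the counts were seen). With spleen references alone they were 4 of 10 and 1 of 10 (Fisher's exact test, p = 0.303). None of the 40 tests passed adjustment, and this was the 1 with an unadjusted p under 0.05.

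The study's main comparison was between genotypes, and it asked whether 1 altered Palb2 allele changed the number or the kind of copy-number changes. The altered share of the autosomes, in segments at least 0.2 from 0, was 9.86% ± 7.80 (SD, n = 15) in Palb2GT/+ and 8.02% ± 7.94 (SD, n = 11) in Palb2+/+ tumours. The difference of 1.85 percentage points had a 95% bootstrap interval from -4.12 to 7.62 (two-sided permutation test, p = 0.556). Single tumours moved it, to 3.23 without T100 (p = 0.298), 0.935 without T095 (p = 0.76) and 0.993 without T560 (p = 0.745). Gained segments covered 8.09% ± 7.03 against 6.28% ± 7.11 of the autosomes (p = 0.523), and lost segments 1.78% ± 1.95 against 1.73% ± 2.56 (p = 0.959). The difference in gained share of 1.80 was 3.26 without T100 (permutation test, p = 0.228) and 0.926 without T560 (p = 0.733). That in lost share of 0.045 was 0.637 without T98 (permutation test, p = 0.412) and -0.199 without T103 (p = 0.825). Breakpoints numbered 25.1 ± 27.6 against 29.1 ± 29.2 per tumour (p = 0.728). Their difference of -4.02 was -14.6 with spleen references alone (p = 0.22) and -10.2 without T176 (p = 0.283), and it turned to 2.07 without T98 (p = 0.86), 1.07 without T143 (Palb2+/+ replicate 11, p = 0.927) and 3.41 before the authors' normalization (p = 0.736). Whole chromosomes changed numbered 0.60 ± 0.74 against 0.55 ± 0.82 (p = 1.0), and focal segments 6.60 ± 5.14 against 7.18 ± 8.54 (p = 0.849). The difference in focal segments of -0.582 turned to 1.6 without T98 (p = 0.447) and 0.40 without T174 (p = 0.912). After adjustment over these 6 values every p was 1.0. Single tumours ranged from 0.018% to 22.6% of the autosomes altered, and both genotypes held 2 tumours with less than 1% altered.

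The genotypes were unevenly spread over the references, with 5 liver references among Palb2GT/+ and 1 among Palb2+/+ tumours. They were also unevenly spread over the Y signal of the tumour channel, relative to the autosomes. Among Palb2+/+ tumours this signal was below 0 only in T100 (-1.194) and T98 (-1.085). Among Palb2GT/+ tumours it was above 0 only in T560, T083, T254, T176 and T103. No comparison between genotypes was made within tumours of like Y signal, so the sex of the animals was not separated from genotype. Among the spleen references alone the difference in altered share was -1.08 percentage points (permutation test, p = 0.745). Within the early batch it was -2.14 (8 against 8 tumours, exact permutation test, p = 0.581), and within the late batch it was 7.98 (7 against 3 tumours, exact permutation test, p = 0.217). For the 6 values the exact p ranged from 0.476 to 1.0 in the early and from 0.217 to 1.0 in the late batch. The noise of the arrays did not separate the genotypes, with a median difference between neighbouring probes of 0.245 ± 0.030 (n = 15) in Palb2GT/+ and 0.248 ± 0.038 (n = 11) in Palb2+/+ arrays (permutation test, p = 0.816).

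**Figure D3:**
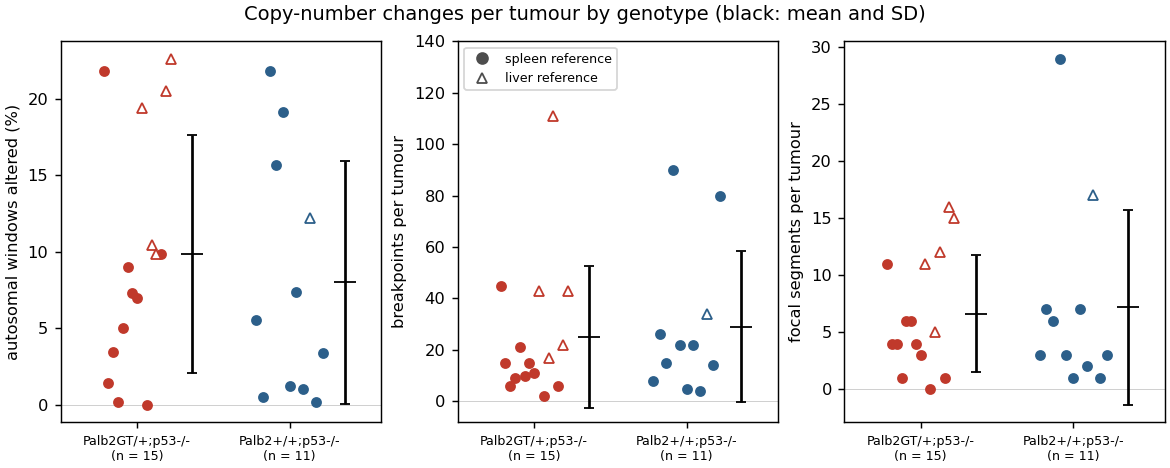
Percent of autosomal windows altered, breakpoints and focal segments (vertical axes) of each lymphoma by genotype (horizontal axis), with circles for spleen and triangles for liver references and black bars for the mean and SD. The group means, 9.86% and 8.02% for the altered share, differed by less than the SD within either group.

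No single chromosome differed between genotypes after adjustment. The 3 with the smallest p were chromosome 1 (0.039 ± 0.065 in Palb2GT/+, n = 15, against -0.0068 ± 0.055 in Palb2+/+, n = 11, permutation p = 0.0745), chromosome 18 (-0.0080 ± 0.059 against -0.050 ± 0.064, p = 0.0972) and chromosome 3 (-0.068 ± 0.049 against -0.041 ± 0.047, p = 0.164), each with an adjusted p of 0.653. The unadjusted 95% bootstrap interval of the difference ran from 0.0007 to 0.0901 for chromosome 1 and left out 0. Those of chromosome 18 (-0.0032 to 0.089) and chromosome 3 (-0.0618 to 0.0099) held 0. Whole gain of chromosome 15 was present in 5 of 15 Palb2GT/+ and 2 of 11 Palb2+/+ tumours (Fisher's exact test, p = 0.658), and whole loss of chromosome 19 in 1 tumour of each genotype (p = 1.0). Over 39439 autosomal windows, limma called 0 different at an adjusted p under 0.05 and 1352 at an unadjusted p under 0.05, of which 761 were higher and 591 lower in Palb2GT/+ tumours (553 higher and 759 lower without further centring). The lowest p, 0.000627, belonged to a window on chromosome 7 at 108629999 with a difference of -0.16 ± 0.042 (SE) and an adjusted p of 0.998. The median half-width of the 95% interval of a window's difference was 0.107.

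The frequency of gains and losses was compared as well. Fisher's exact test per window called 0 windows at an adjusted p under 0.05 for gain or loss and 6 at an unadjusted p under 0.05. Those 6 were neighbours on chromosome 12 from 113880000 to 114239999, and the one with the lowest p was gained in 1 of 15 Palb2GT/+ and 6 of 11 Palb2+/+ tumours (p = 0.0208, adjusted p = 1.0). The ratio there also depended on the reference tissue, at 0.24 ± 0.15 (n = 20) with spleen and -0.087 ± 0.14 (n = 6) with liver (exact permutation test, p = 0.000239). The genotypes differed there by -0.16 over all arrays (permutation test, p = 0.0392) and by -0.12 among spleen references alone (exact permutation test, p = 0.061), in windows that had been chosen by their frequency in the genotypes. None of the 7 recurrent focal regions differed in frequency between genotypes. The loss on chromosome 14 was present in 10 of 15 Palb2GT/+ and 5 of 11 Palb2+/+ tumours (Fisher's exact test, p = 0.426), that on chromosome 6 in 7 and 6 (p = 1.0), that on chromosome 19 in 7 and 3 (p = 0.428), and the gain on chromosome 12 in 3 and 0 (p = 0.238), with adjusted p of 0.778 or more for all 7 regions.

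**Figure D4:**
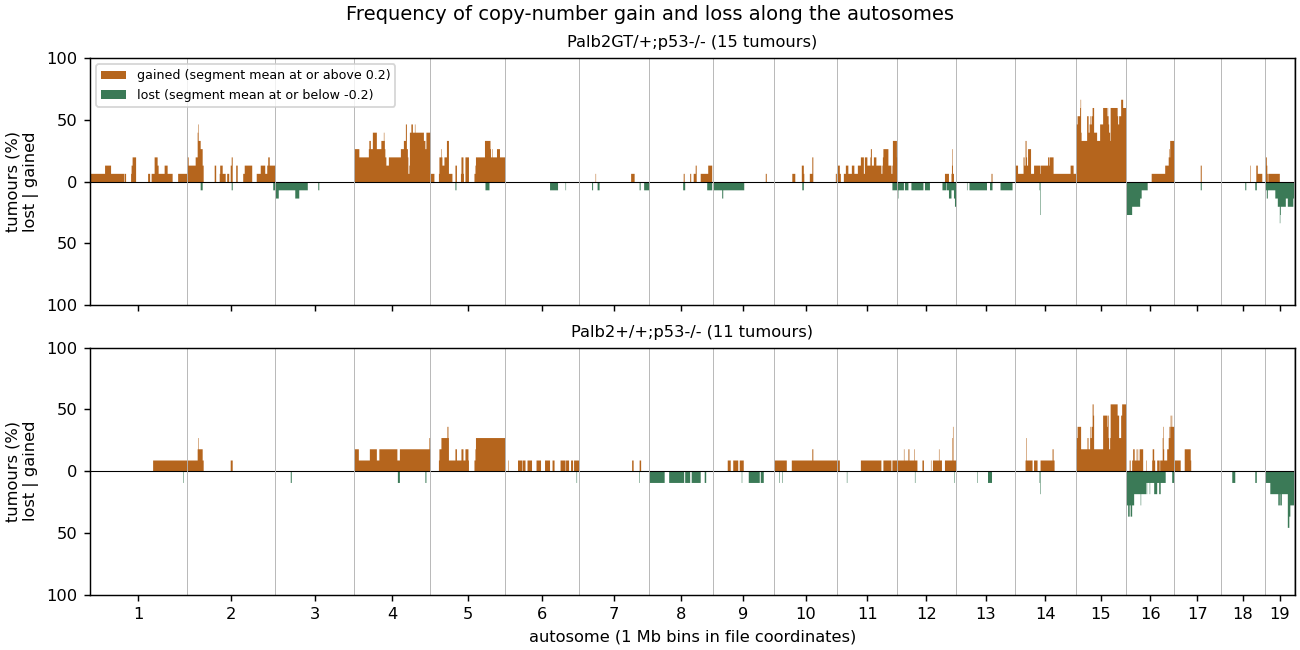
Percent of tumours with a gain (upward) or a loss (downward) in each 1 Mb bin of the autosomes (horizontal axis), for the 15 Palb2GT/+ tumours above and the 11 Palb2+/+ tumours below. A bin counts as gained or lost where most of its windows lie in segments at or beyond 0.2. Gains of chromosomes 4, 5 and 15 and losses of chromosome 19 appear in both genotypes.

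Whether the remaining Palb2 allele was lost in Palb2GT/+ tumours was examined through chromosome 7, which carries Palb2. There was no lost segment anywhere on this chromosome in 12 of 15 Palb2GT/+ and 10 of 11 Palb2+/+ tumours at a threshold of 0.2, and in 8 and 7 tumours at a threshold of 0.1. Among Palb2GT/+ tumours, T560 had lost segments from 25740000 to 25919999 and from 31080000 to 33419999. Tumour T50 (Palb2GT/+ replicate 5) had one from 126360000 to 127739999, and tumour T276 (Palb2GT/+ replicate 9) from 42360000 to 46139999 and from 134520000 to 145135247. The Palb2+/+ tumour was T143, with a lost segment from 125280000 to 126419999. The segments had means from -0.58 to -0.24. Those of T560 held 3 and 22 windows, and the sex chromosomes of this tumour did not match those of its reference. Its losses could therefore also be differences between animals. Segments under 180 kb could not be called, and point mutations or copy-neutral loss are not measured by this assay. For Trp53, 13 of 15 and 9 of 11 tumours had no lost segment on chromosome 11. As all the tumours came from animals without p53, this does not bear on a working Trp53 allele.

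Copy-number changes were larger on arrays with a liver reference than on arrays with a spleen reference. The altered share was 15.8% ± 5.64 (SD, n = 6) with liver and 7.06% ± 7.21 (SD, n = 20) with spleen references (exact permutation test, two-sided, p = 0.0112). The SD of the autosomal segment means was 0.17 ± 0.024 (n = 6) against 0.095 ± 0.044 (n = 20, exact permutation test, p = 0.000469). Focal segments numbered 12.7 ± 4.41 against 5.10 ± 6.24 (exact permutation test, p = 0.0128), and the mean of chromosome 15 was 0.28 ± 0.089 against 0.14 ± 0.12 (exact permutation test, p = 0.0154). With adjustment over the 6 measures compared, these p became 0.0231, 0.00281, 0.0231 and 0.0231. Among the 10 late arrays alone, 6 with liver and 4 with spleen, the differences were 12.5 percentage points for the altered share (exact permutation test, p = 0.0143) and 0.091 for the SD of segment means (exact permutation test, p = 0.00476, the smallest that 210 relabellings allow). Among Palb2GT/+ tumours alone they were 10.05 percentage points (exact permutation test, p = 0.0113) and 0.082 (exact permutation test, p = 0.00366). The difference in chromosome 15 was 0.14 in both subsets and did not pass the threshold in either (exact permutation test, p = 0.081 among late arrays and 0.0703 among Palb2GT/+ tumours). Breakpoints numbered 45.0 ± 34.1 (n = 6) against 21.3 ± 23.9 (n = 20, exact permutation test, p = 0.0521, adjusted p = 0.0625), with a difference of 19.5 among late arrays (exact permutation test, p = 0.433) and 33.2 among Palb2GT/+ tumours (exact permutation test, p = 0.00766). The noise between neighbouring probes was 0.267 ± 0.043 (n = 6) with liver and 0.240 ± 0.027 (n = 20) with spleen references (exact permutation test, p = 0.0696, the same after adjustment), and 0.039 higher with liver among late arrays (exact permutation test, p = 0.114). Of the 7 recurrent focal regions, the loss on chromosome 14 was deeper with liver than with spleen references, at -0.70 ± 0.27 (n = 6) against -0.30 ± 0.33 (n = 20, exact permutation test, adjusted p = 0.0445). Every tumour with a liver reference was among the 15 that define this region. The loss on chromosome 6 was at -0.44 ± 0.18 against -0.34 ± 0.28 (exact permutation test, adjusted p = 0.476), and that on chromosome 19 at -0.20 ± 0.22 against -0.29 ± 0.30, less deep with liver (exact permutation test, adjusted p = 0.508). For the 4 gains the difference ranged from 0.12 to 0.42 (exact permutation test, adjusted p from 0.0441 to 0.476), which depends on the reference of the 3 tumours that define each.

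**Figure D5:**
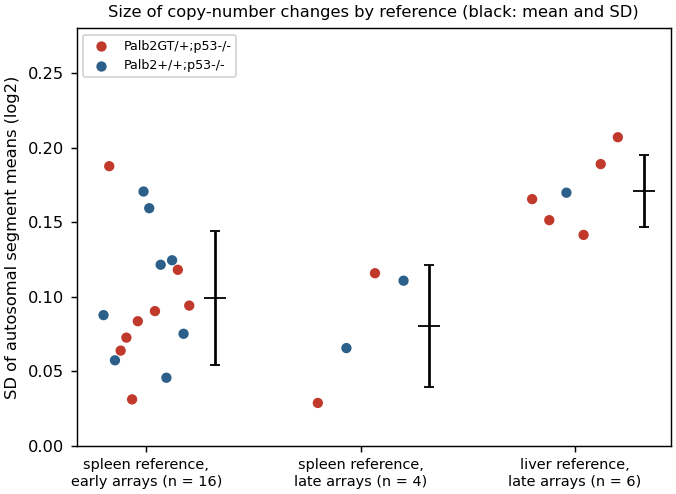
SD of the autosomal segment means in log2 units (vertical axis) of each array, grouped by reference tissue and array batch (horizontal axis) and coloured by genotype, with black bars for the mean and SD. The 6 arrays with a liver reference lie between 0.141 and 0.207, and the 4 late arrays with a spleen reference between 0.029 and 0.116.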

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

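The tests of array batch, of the distal chromosome 12 windows (which were defined again after a first look), of the Y level of the reference and of a Y gain as the only difference in T560, of the T61 label and of other splits of the tumours were chosen after results had been seen. Arrays with a liver reference differed from arrays with a spleen reference in 5 results. The liver minus spleen difference was 8.78 percentage points in the altered share, 0.076 in the SD of segment means, 0.14 in the mean of chromosome 15, 7.57 in focal segments and -0.40 in the chromosome 14 loss region. The difference of 0.25 in the chromosome 2 gain region is not counted, because 2 of the 3 tumours that define this region had a liver reference. Every tumour with a liver reference is likewise among the 15 that define the chromosome 14 loss region. That difference is therefore not independent of how the region was chosen. The ratio at the distal chromosome 12 windows, which were chosen by their frequency in the genotypes, also differed, by -0.32 (exact permutation test, p = 0.000239).

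Array batch as the whole cause is argued against for the SD of segment means, which still differed by 0.0905 among the late arrays (exact permutation test, p = 0.00476). Tumour cells in the spleen of a lymphoma-bearing mouse may have shrunk the ratios, and the reference channel would then carry part of the tumour's own profile. The slope of the reference channel on the tumour's segment means was 0.24 ± 0.76 (n = 20) with spleen. With liver it was -0.058 ± 0.12 (n = 6), a difference of 0.3007 (exact permutation test, p = 0.261). T102 (Palb2GT/+ replicate 10) at 3.26 and T107 (Palb2+/+ replicate 2) at 1.12 dominate the mean and spread with spleen. Their altered shares were 0.018% and 0.492%. In the spleen arrays with the largest altered shares, T560, T100, T115 and T98, the slope ranged from -0.012 to 0.025. There the reference channel carried little of the tumour's profile. Tumour cells in the spleen would lower the altered share, so arrays picked for a large share cannot weigh against this explanation. The high slopes go with the explanation but come from tumours with few changes, so it stays open. Lymphocytes with rearranged DNA in the spleen might raise the ratio at the distal chromosome 12 windows, by lowering the reference signal. Liver minus spleen, that signal differed by 0.0166 over all arrays (exact permutation test, p = 0.909). Among the late arrays it differed by 0.17, lower with spleen as this explanation needs (exact permutation test, p = 0.00952). The tumour signal there differed by -0.26 over all arrays (exact permutation test, p = 0.097) and by -0.14 among the late arrays (exact permutation test, p = 0.11). The difference was thus larger in the tumour channel over all arrays and in the reference channel among the late arrays. This explanation stays open too. A true difference between the tumours of the 6 liver-reference animals and the others is untested.

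Tumour T560 (Palb2GT/+ replicate 1) had a median log2 ratio of 2.40 at the chrY_random probes, which no comparison of the report uses, while the next highest array was at 0.084. Both channels had high Y signal in 13 of the remaining arrays and low signal in 12, whereas in T560 the tumour channel was high (2.11) and the reference channel low (-0.818). That reference level lay 0.143 above the highest reference of the 12 arrays with low signal, nearer to them than to the 13 with high signal, consistent with reference DNA from an animal of the other sex. Its tumour channel lay 0.54 above the highest of the remaining tumour channels, so a gain of Y may add to the ratio, but as the only difference such a gain is argued against by its reference channel, which relative to the lowest reference of the 13 arrays with high Y signal was at -1.209. Which animal the reference came from stays open.

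The labels of T61 (Palb2+/+ replicate 7) disagree on its genotype. If it carried the altered Palb2 allele, its reference DNA would be likely to resemble that of Palb2GT/+ arrays on chromosome 7, given the mixed strain background. A score from the 3 of 20014 chromosome 7 probes that best separated the genotypes in the reference channel of the remaining arrays was -0.815 in T61, against 0.15 ± 0.098 (n = 15) in Palb2GT/+ and -0.74 ± 0.31 (n = 10) in Palb2+/+ arrays, which argues against the Palb2GT/+ label. With probes chosen anew without each array, 24 of 25 arrays lay nearer to their own group. The exception was T105 (Palb2+/+ replicate 1), at 0.28, and whether it carries the altered allele or only a strain variant was not tested.

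For the windows by genotype, the real split gave 0 windows at an adjusted p under 0.05 in limma. Any split gives at least as many, as all 100 of 100 drawn did, so this count decides nothing, and the highest of the other splits gave 298. At an unadjusted p under 0.05 the real split gave 1352 windows and 70 of 100 splits gave as many or more, so chance cannot be excluded for that count. The other splits had a median of 1823 and a highest count of 5724, and what sets this spread was not tested.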

How the results depend on the processing

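Of the alternatives, T560, T98 or T105 left out, segmentation costs of 2 and 6, ratios before the authors' normalization and focal segments measured from their own chromosome were chosen after seeing the data. The genotype differences in the 6 values per tumour did not pass the threshold under any alternative (lowest p 0.0985, for the gained share), so the changes of sign that follow are between differences within the spread. With spleen references only, the difference (Palb2GT/+ minus Palb2+/+, percentage points) was -1.08 in the altered, -0.851 in the gained and -0.230 in the lost share. With a threshold of 0.1 it was -1.94, -0.652 and -1.29, and -1.67 in whole chromosomes. The lost share also turned to -0.0697 with the array batch as a block, -0.137 without the 2 noisiest arrays, -0.110 without T105, -0.123 with a threshold of 0.3, -1.44 with centring on the mode and -0.0921 with a cost of 6, under which whole chromosomes turned to -0.0606. Without T98, breakpoints turned to 2.07 and focal segments to 1.6. Other single tumours also turned small differences, such as T143 for breakpoints (1.07) and T174 for focal segments (0.40). On ratios before the authors' normalization, breakpoints were at 3.41, focal segments at 0.358 and whole chromosomes at -0.103. The causes were not tested. No alternative gave a chromosome or a window that differed by genotype after adjustment. For losses on chromosome 12, a test and alternatives chosen after seeing the data, Fisher's exact p was 0.428 with a threshold of 0.1 and 0.0237 with 0.3 (adjusted p 0.967 and 0.95). The number of recurrent focal regions, 7, became 16 with a focal threshold of 0.3, 4 with at most 1 Mb, 3 with at least 5 tumours, 3 with spleen references only and 14 with a cost of 2; the stricter criteria and the smaller number of tumours remove regions by construction. Chromosome X turned to 0.058 on ratios before normalization, and the cause was not tested. Of the calls in all tumours, chromosomes 6, 7 and 8 were also lost with spleen references only (adjusted p = 0.344, 0.148 and 0.227), and chromosome 6 on ratios before normalization (0.0646). The reference tissue differences in altered share and SD of segment means kept their direction and side of the threshold within the late arrays, within Palb2GT/+ tumours and before normalization. The alternatives for named loci were not run, as loci were not placed. No paired analysis was possible because the replicate numbers only name the tumours. The array noise limits small changes. On simulated profiles with a change of 0.2, a segment mean of 0.1 was enough to count as found. Such segments were found in 1.0% of those of 3 windows and 52.9% of those of 10.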

Other observations

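The test of breakpoint clustering was chosen after the profiles had been seen, and its random spread was changed from single breakpoints to pairs after a first run. Breakpoints were concentrated on single chromosomes in some lymphomas. In T98 (Palb2+/+ replicate 4), 74 of 90 breakpoints lay on chromosome 16, which holds 4.01% of the autosomal windows and carried its 8 amplified segments. In T107 (Palb2+/+ replicate 2) all 26 breakpoints lay on chromosome 12, and in T174 (Palb2+/+ replicate 9) 25 of 34 lay on chromosome 16. A spread of pairs of breakpoints by chromosome length gave as many on 1 chromosome in none of 10000 draws for each of these 3 tumours (p = 0.0001, the smallest the draws can give, Benjamini-Hochberg adjusted p = 0.000867). In all, 7 of 26 tumours had an adjusted p under 0.05, 3 of them Palb2GT/+ and 4 Palb2+/+. The remaining ones were T61 and T113 on chromosome 14, T665 on chromosome 19 and T276 on chromosome 2. Chromosomes 14 and 19 held recurrent focal losses, and chromosomes 2, 12 and 16 held recurrent focal gains. T174 and T276 were among the tumours that define the gains on chromosomes 16 and 2. A spread by chromosome length does not allow for such recurrent regions. A local event that broke 1 chromosome many times is a candidate explanation, which the ratios alone do not separate from stepwise amplification.

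T-cell receptor rearrangement may account for the focal losses on chromosomes 6 and 14, the chromosomes of Tcrb and of Tcra and Tcrd. Deletion between fixed gene segments would end at nearly the same place in every tumour. The end coordinate was the tighter boundary for all 3 losses. On chromosome 6 it was the same window, ending at 41459999, in all 13 tumours, and on chromosome 14 it lay between 53099999 and 53159999 in all 15. On chromosome 19 it ranged from 32879999 to 33659999 over 10 tumours. The mean distance from the median end was 8.6 kb for the 28 segments on chromosomes 6 and 14 and 156.0 kb for the 10 on chromosome 19, a difference of -147.4 kb (permutation test, two-sided, p = 4e-05). This p treats the segments as independent, although 9 tumours gave 2 of the 28 and some also had the loss on chromosome 19, and it compares 2 regions with 1, so it is too small. The start on chromosome 14 varied more, from 52260000 to 52920000. These values are consistent with a locus with fixed ends, but boundaries are resolved to 60 kb only and the loci themselves were not placed in the files' build.

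Tumour T665 (Palb2GT/+ replicate 3) had a chromosome X median of -0.344 with a chrY_random median of 0.079. The array pair with the highest correlation was T560 and T254 (Palb2GT/+ replicate 11), at 0.632.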
